A study of Mus musculus with 4 samples.

How the data were processed

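RNA from FACS-sorted prostate luminal cells was profiled in 4 libraries, 2 labelled AR_KO and 2 labelled control. Per the labels' protocols, total RNA was purified with a NucleoSpin kit, turned into cDNA with the NuGEN Ovation V2 system, which primes at random and at poly(A) tails and does not mark strand, made into libraries with a TruSeq DNA kit and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, bcl2fastq 1.8.3, TopHat and Cufflinks were used with the mm10 (GRCm38) build. Versions of the latter pair and their options were not given in the sources used here.

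Per the file headers, the authors deposited a Cufflinks tracking table for each library, with an FPKM (fragments mapped to a transcript, relative to its length and to all mapped fragments), the bounds of its interval and a status for each of 63241 UCSC transcripts. The deposited tables also list a coverage (signal) per transcript, which was used only to compare the depth of the libraries. FPKM values are not counts, so no count test was run. Cufflinks divides reads that overlap several transcripts between them by estimate, so a value of 0 can be a failed or shifted estimate. Genes with an exact 0 are given as listed at 0, with each library's value. Depth was estimated by taking the interval's half-width as 2 SD of a Poisson count, which gave 12094000, 13193300, 9652950 and 10053000 fragments in AR_KO replicates 1 and 2 and control replicates 1 and 2. This covers counting error only and rests on that reading of the intervals.

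The tables give no gene names. Each transcript was matched to a gene by its coordinates against the GENCODE vM21 annotation of GRCm38 and RefSeq gene extents, and 56095 of 63241 transcripts (88.7%) received a symbol, with 97.9% of the summed FPKM. Of the 14061 transcripts with a mean of at least 1 FPKM, 13923 (99.0%) received one. Transcripts of a symbol were summed. Sbp, Svs5 and Tpm3, which carried a status other than OK in at least 1 control library (too many fragments for Sbp and Svs5, a failed estimate for 7 transcripts of Tpm3), were left out of the tests.

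Genes with a mean over the 4 libraries of at least 1 FPKM were tested. Values were log2(FPKM + 1), as deposited and with no further scaling. A fold change on this scale understates the change of genes with low values. AR_KO was compared with control by limma 3.58.1 (eBayes with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test has 3 splits of 4 libraries and cannot reach 0.05. A description without a test counted genes whose groups did not overlap and whose mean log2 values differed by at least 1. In the text, values are mean ± SD of FPKM over n = 2 libraries per group, log2 fold changes are AR_KO minus control with their standard error, and rose or fell refers to genes past the limma test.

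Before the data were examined, 30 gene lists were written from general knowledge of the prostate, among them markers of other cell types the sort could hold. Each list with at least 5 measured genes was tested by camera with a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the residuals and by fry. With an estimated correlation the test has only the residual degrees of freedom of 4 libraries. Hardly any list could pass it, so its adjusted p does not show that correlation between genes removed a result. Members were also adjusted over the list alone. The genes named were Ar, the 12 with the largest rise and the 12 with the largest fall among those past the test with non-overlapping groups (unnamed models and small RNAs left out), and for each list up to 4 members with the smallest p and up to 4 more with the highest mean. Gene families grouped by the start of their symbol were chosen after values were seen. Copies of near-identical genes, such as the kallikreins, secretoglobins, hemoglobins, small proline-rich and MHC genes, can share reads, so that their values are uncertain.

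The alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, leaving out each library, the sample number as a block, limma without the trend and the highest transcript of a gene alone. Leaving out genes listed at 0 in any library was added after the data were seen. The steps were tested on simulated data of the 10813 genes with the real means and spread, of which 200 were changed. Of 100 genes changed 2-fold, 37 were recovered, and of 100 changed 1.5-fold, 17, with 2 false calls. Far more genes passed in the real data, which eases the adjusted threshold, so these are not the shares recovered there. With no effect, 0 genes and 0 lists were called by limma and camera. The simulated genes were independent of each other, so this does not show how often camera would call lists of correlated genes. Tables were handled in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.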

Results

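RNA was profiled by sequencing in luminal cells that had been sorted by FACS from mouse prostate, in order to look for signals outside the cell that drive epithelial proliferation once the androgen receptor (AR) is lost. The luminal cells are the secretory cells that line the prostate glands. In K8-CreERT2;ARfl/Y mice, a Cre recombinase that tamoxifen switches on is made in cells expressing keratin 8 and recombines a floxed Ar allele. Littermate K8-CreERT2 mice, without the Ar genotype named for the knockout, served as controls. Both kinds of mice were 8 weeks old and received tamoxifen at 9 mg per 40 g per day for 4 days. The 4 libraries fell into 2 groups, AR_KO and control, with 2 libraries in each. The labels did not say how many animals went into a library, so the p-values measure the spread between these libraries, which may be partly technical.

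Each library listed an FPKM for 63241 transcripts of the UCSC annotation on the mm10 (GRCm38) mouse build. The intervals listed beside the FPKM values implied about 12094000 and 13193300 fragments in AR_KO replicates 1 and 2, and 9652950 and 10053000 in control replicates 1 and 2. Sbp in both control libraries and Svs5 in control replicate 2 carried no value and are missing from these totals. The median gene listed near 1 FPKM rested on 45.7 to 57.5 implied fragments. At least 1 FPKM was found for 11000 and 10993 genes in the AR_KO libraries and for 10381 and 10388 in the control libraries. With Sbp, Svs5 and Tpm3, which lacked an accepted value in a control library, left out of all 4 libraries, the 10 most abundant genes held 28.1% and 28.05% of the summed FPKM in AR_KO and 42.3% and 41.3% in control. Across genes, log2 values correlated with r = 0.989 within AR_KO, 0.984 within control and 0.950 to 0.952 between groups (Pearson, genes not being independent replicates). Libraries of one group differed by more than the sampling of fragments, with a mean chi-square per gene of 3.24 in AR_KO and 4.39 in control, so neither pair was 1 library listed again. This does not show that they came from separate animals or preparations of RNA.

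Ar itself, the gene targeted by the recombination (chrX:98148769-98323215, plus strand), was listed at 5.38 and 6.04 FPKM in the AR_KO libraries and at 10.1 and 8.83 FPKM in the control libraries. The log2 fold change was −0.64 ± 0.12 (SE, n = 2 per group, limma adjusted p = 0.00647). The value joined 2 transcripts. One runs along all 8 exons (uc009tuv.1, chrX:98149750-98317147), and was listed at 2.86 and 3.30 FPKM in AR_KO against 5.09 and 4.24. The other is a single-exon transcript inside the 3′ UTR in exon 8 (uc009tuw.1, chrX:98320098-98322780), listed at 2.52 and 2.74 FPKM against 5.03 and 4.58. Which exon the recombination removed was not given in the labels. Reads from exons that remained in place counted towards both values, so the UTR transcript did not check the deletion. The call was lost without AR_KO replicate 1 (log2 fold change −0.57, adjusted p = 0.0841), without AR_KO replicate 2 (−0.71, adjusted p = 0.0547) and with the longer transcript alone (−0.47, adjusted p = 0.0782).

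The comparison of AR_KO with control addresses what the sorted luminal fraction expressed after tamoxifen in mice with the floxed Ar allele. Most measured secretory products of the prostate fell and most measured cytokine, chemokine and NF-kB target genes rose in AR_KO. Stromal markers (15 of 15) and macrophage markers (10 of 11) rose in the same libraries. Spink1 (chr18:43728082-43737557, minus strand), a trypsin inhibitor of the prostatic secretion, had the highest mean FPKM in control of the genes tested and stood at 5230.0 ± 81.5 FPKM in AR_KO and 103438 ± 4745 FPKM in control (SD, n = 2 each), 19.8-fold lower. Sbpl (chr17:23953084-23955274, minus strand), related to spermine-binding protein, fell 27.2-fold. In the other direction, Saa3 (chr7:46711998-46715700, minus strand), an acute-phase serum amyloid, stood at 171 ± 2.37 FPKM in AR_KO and 5.28 ± 2.47 FPKM in control, and Klk1 (chr7:44225360-44229618, plus strand), a kallikrein protease, at 410.0 ± 23.1 FPKM in AR_KO and 13.7 ± 2.85 FPKM in control. The keratin gene Krt18 (chr15:102028180-102032027, plus strand), a luminal marker, rose 2.67-fold, from 991 ± 16.1 to 2651 ± 34.6 FPKM.

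Of 10813 genes with a mean of at least 1 FPKM, 4154 (38.4%) passed the limma test at an adjusted p under 0.05, 3354 of them higher in AR_KO and 800 lower. At a change of 2-fold or more, 541 genes were higher and 123 lower. The median of all 10813 genes lay at a log2 fold change of 0.20 on the deposited scale. With median-of-ratios scaling, which shifted the log2 fold changes of genes by a median of −0.21, 3365 genes passed, 1571 higher and 1794 lower. With quantile normalization (median shift over genes −0.26) 2893 passed, 1457 higher and 1436 lower. Both the deposited values and median-of-ratios scaling called 1571 genes higher and 800 lower in the same direction, 383 and 123 of them by 2-fold or more. Since median-of-ratios scaling lowers AR_KO against control for every gene, this overlap follows largely from the shift and is no independent agreement. Without a test, 677 genes had non-overlapping groups and mean log2(FPKM + 1) values at least 1 apart (2-fold), 551 higher and 126 lower. The other 2 ways to divide the 4 libraries into pairs gave 15 and 17, but each puts an AR_KO with a control library, so these counts do not measure chance. With no effect, 33.3% of genes would have non-overlapping groups at any fold. The count of genes 2-fold apart was 1094 and 245 with a pseudocount of 0.1 and 5 in place of 1, and 356 among genes with a mean of at least 5 FPKM. The count of genes past the test was 1553 without AR_KO replicate 1 and 1499 without AR_KO replicate 2.

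**Figure D1:**
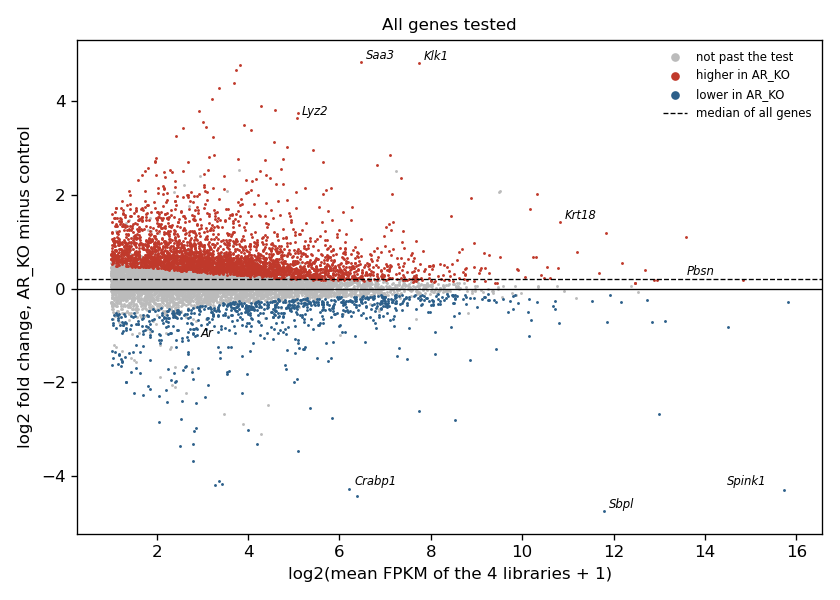
Log2 fold change (AR_KO minus control, y axis) against log2 of the mean FPKM of the 4 libraries plus 1 (x axis) for the 10813 genes tested, one point each. Red and blue points passed the limma test as higher (3354) or lower (800) in AR_KO, grey points did not, and the dashed line marks the median of all genes at 0.20.

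Among the 12 named genes with the largest rise, Cadps, a regulator of vesicle exocytosis, was listed at 23.6 ± 1.41 against 0.168 ± 0.0679 FPKM in AR_KO and control, and Lor, the cornified-envelope protein loricrin, at 16.5 ± 0.142 against 0.0506 ± 0.0211 FPKM. The iron-binding protein lactoferrin (Ltf) stood at 35.7 ± 0.141 against 1.47 ± 0.197 FPKM, the lysozyme gene Lyz2 at 61.1 ± 4.27 against 3.99 ± 0.397 FPKM and Fxyd4, a regulator of the sodium pump, at 62.3 ± 1.902 against 3.71 ± 0.250 FPKM. Prss23os, at 43.7 ± 5.64 against 2.15 ± 0.279 FPKM, overlaps Prss23 on the other strand, and the library did not mark strand, so its reads cannot be told from those of Prss23. Txnrd2 (27.05 and 25.9 FPKM in the AR_KO libraries), Ifi27l2a (21.9 and 27.2), Lipf (19.1 and 17.96) and Tagln (10.1 and 16.2) were listed at 0 in both control libraries, so no fold was given. Txnrd2 and Tagln share exon sequence positions with Comt and Pcsk7 on the opposite strand. Among the 12 largest falls were Spink5, another serine protease inhibitor, at 6.33 ± 0.574 against 158 ± 2.48 FPKM, and the retinoic-acid-binding protein Crabp1 at 6.34 ± 1.299 against 140.5 ± 4.47 FPKM. The metalloproteinase inhibitor Timp4 stood at 4.65 ± 0.346 against 61.9 ± 0.609 FPKM, the potassium channel Kcnk3 at 2.36 ± 0.0888 against 32.5 ± 0.993 FPKM and C2cd4a at 0.531 ± 0.0614 against 11.6 ± 0.371 FPKM. The secretoglobin genes fell with them. Scgb2b17 stood at 0.130 ± 0.0526 against 19.5 ± 1.25 FPKM and Scgb2b15 at 0.130 ± 0.0526 against 18.6 ± 0.896 FPKM, values that are uncertain because the genes of this family are near-identical. Scgb2b7 was listed at 0 and 0.594 FPKM in AR_KO and at 11.9 and 11.4 FPKM in control. Lppos (17.9 and 16.6 FPKM in the control libraries) and Htra2 (11.2 and 12.6) were listed at 0 in both AR_KO libraries and overlap Lpp and Aup1 on the opposite strand.

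**Figure D2:**
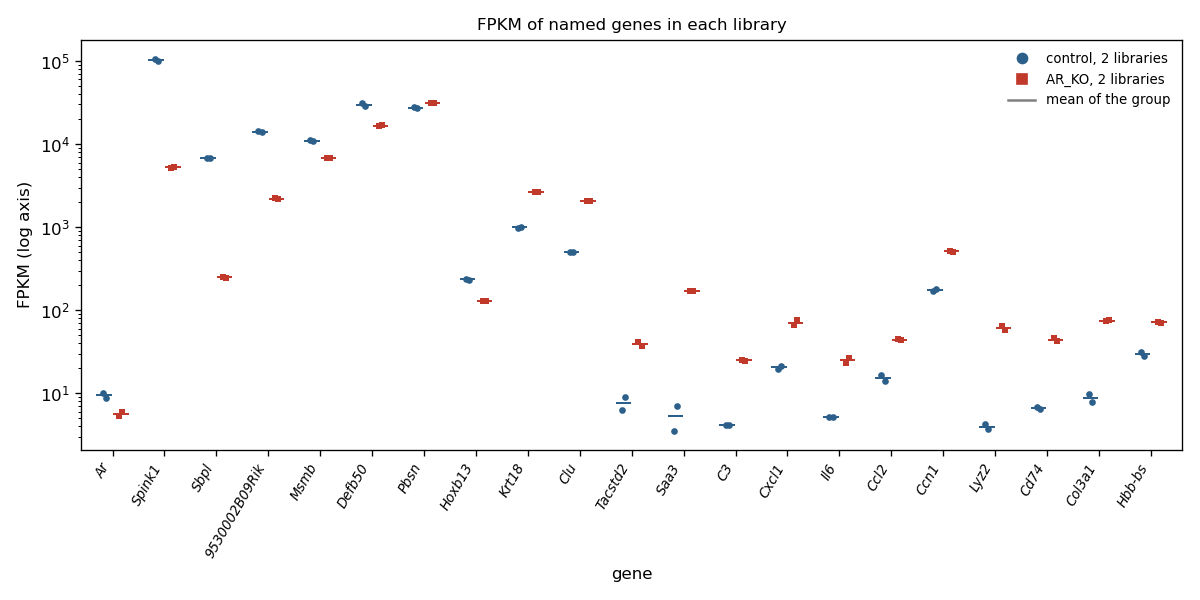
FPKM on a log axis (y) of 21 named genes (x) in each of the 4 libraries, blue circles for control and red squares for AR_KO, with a bar at each group's mean. Spink1 falls from 103438 to 5230.0 FPKM and Saa3 rises from 5.28 to 171.

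Of the secretory products of the prostate, 7 of 21 measured members rose and 13 fell (7 rose and 13 fell when adjusted over the list alone), with a median log2 fold change of −0.43 and a camera adjusted p of 2.66e-08 (adjusted p = 0.21 with an estimated correlation). Besides Spink1 and Sbpl, the secreted product encoded by 9530002B09Rik fell from 14157 ± 434 to 2211 ± 19.5 FPKM, beta-microseminoprotein (Msmb) was listed at 6829.8 ± 44.4 FPKM in AR_KO and 10978 ± 123 FPKM in control, and the defensin Defb50 at 16699 ± 274 FPKM in AR_KO and 29735 ± 1941 FPKM in control. With quantile normalization Defb50 stood at −0.03 on the log2 scale and did not pass. Probasin (Pbsn), a classical androgen-driven gene of the mouse prostate, was listed at 31004 ± 100.1 FPKM in AR_KO and 27454 ± 659.8 FPKM in control, a log2 fold change of 0.18 ± 0.02 (adjusted p = 0.00139) that turned to −0.06 (adjusted p = 0.112) with median-of-ratios scaling and was 1.06 with quantile normalization. Quantile normalization assigns values by rank, and Pbsn and Defb50 ranked below Spink1 in control and above it in AR_KO. The 1.06 is therefore not a doubling of the FPKM of Pbsn. Spermine-binding protein (Sbp, uc008auc.1, chr17:23941996-23945607) was listed at 9242 and 8980 FPKM in AR_KO and carried a status of too many fragments, with a value of 0, in both control libraries, so that no fold was computed.

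Genes known to be induced by androgen moved in both directions. Of this list, 15 of 31 measured members rose and 6 fell (15 rose and 6 fell when adjusted over the list alone), and with median-of-ratios scaling 10 rose and 10 fell. The median log2 fold change was 0.25, near that of all genes, and the camera test, whose direction was down, did not pass (adjusted p = 0.818, and adjusted p = 0.85 with an estimated correlation). Azgp1, a secreted zinc-binding glycoprotein, fell from 444 ± 7.06 to 250.1 ± 6.45 FPKM, whereas the stress-responsive gene Ndrg1 (12.5 ± 0.449 against 2.16 ± 0.0835 FPKM), the kinase gene Sgk1 (493 ± 7.18 against 285 ± 8.32 FPKM) and the kallikrein gene Klk1b27 (220.1 ± 2.81 against 109.7 ± 5.37 FPKM) rose. Nkx3-1, the prostate homeobox gene, stood at 135 ± 4.92 against 108 ± 5.71 FPKM (adjusted p = 0.00498, and 0.342 with median-of-ratios scaling). Of the steroid receptors and steroid enzymes, 2 of 10 measured members rose and 1 fell (2 rose and 1 fell when adjusted over the list alone). The one that fell was Ar, and the estrogen receptor gene Esr1 (7.396 ± 0.170 against 4.56 ± 0.722 FPKM) was among those that rose. With median-of-ratios scaling and with quantile normalization 0 rose and 3 fell, and Esr1 did not pass (adjusted p = 0.0639 and 0.116). That list's median was 0.21 and its camera direction down (adjusted p = 0.473, and adjusted p = 0.549 with an estimated correlation).

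Luminal identity genes mostly rose. Of the luminal epithelial markers, 15 of 17 measured members rose and 2 fell (15 rose and 2 fell when adjusted over the list alone), and with median-of-ratios scaling 11 rose and 2 fell. The list's camera adjusted p was 5.45e-04 (adjusted p = 0.21 with an estimated correlation). Krt19 stood at 1558 ± 30.1 against 972 ± 22.4 FPKM, Krt8 at 572 ± 6.75 against 419 ± 7.503 FPKM and the surface protein gene Prom1 at 127 ± 4.35 against 77.1 ± 4.81 FPKM, while the prostate homeobox gene Hoxb13 fell from 235 ± 3.19 to 130.1 ± 0.901 FPKM. Of the markers of the proximal luminal cells that are high in Sca-1, 10 of 15 measured members rose and 1 fell (10 rose and 1 fell when adjusted over the list alone), with a median of 0.52. Tested as a set, the adjusted p from camera was 0.0131 (adjusted p = 0.29 with an estimated correlation). The list call was lost without control replicate 2 (adjusted p = 0.0688). Clusterin (Clu) rose from 505 ± 1.54 to 2059 ± 4.801 FPKM, Tacstd2 (Trop2) from 7.71 ± 1.88 to 39.5 ± 3.61 FPKM and Ly6a, which encodes Sca-1, from 11.9 ± 0.449 to 27.7 ± 1.85 FPKM, while the cytochrome P450 gene Cyp2f2 fell (log2 fold change −0.40 ± 0.09). In the same libraries 8 of 9 basal and 15 of 15 stromal markers rose, and 0 of either list fell, on the deposited scale. With median-of-ratios scaling 1 basal marker fell.

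Of the NF-kB target genes, 20 of 23 measured members rose and 0 fell (21 rose and 0 fell when adjusted over the list alone), with a median of 0.83, and with median-of-ratios scaling 15 rose and 0 fell. By camera the adjusted p was 2.38e-07 (adjusted p = 0.21 with an estimated correlation). Complement C3 stood at 25.04 ± 0.494 against 4.19 ± 0.00194 FPKM, the transcription factor gene Cebpb, which overlaps Tmem189 on the other strand, at 83.8 ± 2.23 against 36.9 ± 0.522 FPKM and the NF-kB inhibitor gene Nfkbia at 109 ± 0.240 against 66.7 ± 4.91 FPKM. Of the cytokines and chemokines, 18 of 26 measured members rose and 1 fell (20 rose and 1 fell when adjusted over the list alone), with a median of 1.22. As a list, the camera adjusted p came to 1.58e-04 (adjusted p = 0.21 with an estimated correlation). The neutrophil-attracting chemokine genes Cxcl1 (71.1 ± 5.98 against 20.6 ± 1.37 FPKM) and Cxcl5 (13.8 ± 0.424 against 1.57 ± 0.266 FPKM), the monocyte-attracting Ccl2 (44.2 ± 1.02 against 15.4 ± 1.69 FPKM) and the interleukin gene Il6 (24.9 ± 2.29 against 5.22 ± 0.0597 FPKM) rose, and Cxcl17 fell (6.02 ± 0.732 against 23.7 ± 1.37 FPKM). Markers of macrophages and stromal cells rose in the same libraries, with median log2 fold changes of 1.47 and 1.802.

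Of the MHC class II list, 6 of 7 measured members rose and 0 fell (6 rose and 0 fell when adjusted over the list alone). The values included Cd74, the invariant chain, at 44.2 ± 2.43 against 6.696 ± 0.286 FPKM and H2-Ab1 at 17.1 ± 1.07 against 3.21 ± 1.27 FPKM. Camera gave this list an adjusted p of 0.0131 (adjusted p = 0.3 with an estimated correlation). These genes are typical of macrophages and dendritic cells, whose markers rose with them. Of the MHC class I list, 11 of 13 measured members rose and 1 fell (11 rose and 2 fell when adjusted over the list alone), a set that did not pass as a whole. The list's camera adjusted p was 0.0825 (adjusted p = 0.429 with an estimated correlation). With median-of-ratios scaling 5 rose and 2 fell. Of the interferon-response genes, 14 of 25 measured members rose and 3 fell (14 rose and 3 fell when adjusted over the list alone), for example Ifit3 (6.17 ± 0.561 against 1.01 ± 0.489 FPKM) and Isg15 (16.2 ± 0.779 against 6.77 ± 1.53 FPKM), whereas Bst2 fell (33.98 ± 1.17 against 40.1 ± 2.21 FPKM). With quantile normalization 9 rose and 3 fell. That set did not pass either. Tested as a set, the adjusted p from camera was 0.0698 (adjusted p = 0.3 with an estimated correlation).

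Of the growth factors and secreted ligands, the class of signals named in the study's purpose, 17 of 27 measured members rose and 0 fell (18 rose and 0 fell when adjusted over the list alone), with a median of 0.67. By camera the adjusted p was 0.00161 (adjusted p = 0.21 with an estimated correlation). With median-of-ratios scaling 14 rose and 1 fell, and with quantile normalization 11 rose and 0 fell. Markers of other cell types rose in the same libraries, 15 of 15 for stroma, 10 of 11 for macrophages and 5 of 6 for endothelium. The matricellular proteins Ccn1 (Cyr61) and Ccn2 (Ctgf) stood at 517 ± 10.2 against 176 ± 6.78 FPKM and 14.4 ± 0.521 against 1.300 ± 0.973 FPKM, the stress-induced ligand Gdf15 at 240.1 ± 3.31 against 141 ± 10.03 FPKM and the vascular growth factor Vegfa at 40.2 ± 1.403 against 22.2 ± 1.31 FPKM. Bmp7 was listed at 15.3 ± 0.190 against 15.3 ± 1.28 FPKM and did not pass (adjusted p = 0.942). Of the cell proliferation genes, 1 of 21 measured members rose and 1 fell, namely Mcm4 (3.04 ± 0.454 against 1.597 ± 0.137 FPKM) and the ribonucleotide reductase gene Rrm2 (2.83 ± 0.0874 against 6.099 ± 0.170 FPKM). When adjusted over the list alone 0 rose and 1 fell. Mcm4 did not pass with median-of-ratios scaling (adjusted p = 0.0605) or quantile normalization (adjusted p = 0.138), and with the latter 0 rose and 3 fell. The list's median was 0.21, its camera direction down (adjusted p = 0.318, and adjusted p = 0.429 with an estimated correlation).

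Of the tight and adherens junction genes, 21 of 33 measured members rose and 2 fell (23 rose and 2 fell when adjusted over the list alone), among them F11r (83.9 ± 0.0887 against 55.3 ± 2.66 FPKM), Tjp2 (28.9 ± 1.79 against 14.4 ± 0.284 FPKM) and the polarity gene Pard6b (19.01 ± 1.001 against 6.86 ± 0.762 FPKM), while the claudin gene Cldn10 fell from 265 ± 0.887 to 92.8 ± 5.24 FPKM. Camera gave an adjusted p of 0.00501 (adjusted p = 0.21 with an estimated correlation). With median-of-ratios scaling 12 rose and 4 fell. Of the p53 and apoptosis genes, 13 of 20 measured members rose and 0 fell (15 rose and 0 fell when adjusted over the list alone). Listed here were the cell-cycle inhibitor gene Cdkn1a at 46.7 ± 0.348 against 27.5 ± 0.621 FPKM and the death receptor gene Fas at 17.3 ± 1.96 against 8.47 ± 1.28 FPKM. With the highest transcript of each gene alone, the list of p53 and apoptosis genes did not pass (adjusted p = 0.0501). With median-of-ratios scaling 8 rose and 0 fell. As a list, the camera adjusted p came to 0.0131 (adjusted p = 0.3 with an estimated correlation). Of the genes induced by cell dissociation and other early stimuli, 12 of 24 measured members rose and 4 fell (12 rose and 4 fell when adjusted over the list alone), and the set did not pass. With median-of-ratios scaling the balance turned, and 7 rose and 12 fell, with a median of −0.14 in place of 0.09, whereas with quantile normalization 11 rose and 6 fell. Camera gave this list an adjusted p of 0.598 (adjusted p = 0.833 with an estimated correlation). Nr4a1 (184 ± 0.296 against 73.5 ± 1.71 FPKM) and Socs3 (13.6 ± 0.227 against 4.38 ± 0.576 FPKM) rose.

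Of the oxidative stress and glutathione genes, 11 of 21 measured members rose and 4 fell (12 rose and 4 fell when adjusted over the list alone). Members included the secreted peroxidase Gpx3 at 16876 ± 47.3 against 7892 ± 159 FPKM and the glutathione transferase Mgst1 at 60.8 ± 0.829 against 13.1 ± 2.49 FPKM. With median-of-ratios scaling 7 rose and 5 fell. The list's camera adjusted p was 0.179 (adjusted p = 0.378 with an estimated correlation). Of the cholesterol and fatty acid synthesis genes, 2 of 24 measured members rose and 5 fell (1 rose and 4 fell when adjusted over the list alone). With median-of-ratios scaling 0 rose and 11 fell, and with quantile normalization 0 rose and 10 fell. Among them were Insig1 at 11.1 ± 0.555 against 20.2 ± 0.709 FPKM and Idi1 at 8.36 ± 0.741 against 15.4 ± 0.194 FPKM, which fell. Tested as a set, the adjusted p from camera was 5.10e-04 (adjusted p = 0.21 with an estimated correlation). In polyamine metabolism, a pathway that feeds the spermine of the prostatic fluid, 2 of 12 measured members rose and 4 fell (2 rose and 4 fell when adjusted over the list alone). The biosynthetic genes Odc1 (18.1 ± 0.454 against 36.7 ± 2.05 FPKM) and Srm (70.2 ± 0.856 against 105 ± 0.464 FPKM) fell, and Azin1 (171 ± 2.43 against 78.2 ± 0.185 FPKM) and the catabolic Sat1 (197 ± 5.07 against 124 ± 2.28 FPKM) rose. The polyamine median was 0.01, its mean −0.00536 and its camera direction down (adjusted p = 0.0741, and adjusted p = 0.429 with an estimated correlation). Of the endoplasmic reticulum and secretory machinery genes, 7 of 28 measured members rose and 9 fell (8 rose and 13 fell when adjusted over the list alone). Ssr4 fell (855 ± 20.5 against 1068 ± 33.1 FPKM). With median-of-ratios scaling 1 rose and 17 fell. Camera gave a direction of down (adjusted p = 9.32e-04, and adjusted p = 0.29 with an estimated correlation). Of the ribosomal protein genes, 1 of 82 measured members rose and 30 fell (1 rose and 30 fell when adjusted over the list alone), with a median of −0.13, and with median-of-ratios scaling 0 rose and 64 fell. By camera the adjusted p was 1.44e-16 (adjusted p = 0.21 with an estimated correlation). Of the mitochondrially encoded genes, 3 of 7 measured members rose and 2 fell (3 rose and 2 fell when adjusted over the list alone), a count that became 0 rises and 5 falls with median-of-ratios scaling, and 3 rises and 1 fall with quantile normalization. Their median was −0.04, their mean 0.000544 and their camera direction down (adjusted p = 0.237, and adjusted p = 0.532 with an estimated correlation).

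Markers of cells other than luminal cells were also higher in AR_KO. Of the stromal markers, 15 of 15 measured members rose and 0 fell (15 rose and 0 fell when adjusted over the list alone), and with median-of-ratios scaling 13 rose and 0 fell. Listed here were the collagen genes Col3a1 at 75.3 ± 2.71 against 8.84 ± 1.22 FPKM and Col1a1 at 31.6 ± 1.07 against 4.71 ± 0.428 FPKM, and decorin (Dcn) at 186 ± 2.14 against 141 ± 3.702 FPKM. As a list, the camera adjusted p came to 2.66e-08 (adjusted p = 0.21 with an estimated correlation). Of the macrophage and dendritic cell markers, 10 of 11 measured members rose and 0 fell (10 rose and 0 fell when adjusted over the list alone). Members included C1qb at 5.83 ± 0.737 against 1.02 ± 0.253 FPKM and Cd14 at 15.4 ± 0.103 against 4.995 ± 1.400 FPKM beside Lyz2. Camera gave this list an adjusted p of 3.96e-04 (adjusted p = 0.21 with an estimated correlation). Of the basal epithelial markers, 8 of 9 measured members rose and 0 fell (8 rose and 0 fell when adjusted over the list alone). Among them were Krt15 at 43.6 ± 0.462 against 19.3 ± 2.99 FPKM and Krt14 at 15.99 ± 2.096 against 6.82 ± 0.103 FPKM. Median-of-ratios scaling left 6 that rose and 1, Dst, that fell (log2 fold change −0.51, limma adjusted p = 0.0455). The list's camera adjusted p was 0.0111 (adjusted p = 0.3 with an estimated correlation). Of the red blood cell markers, 5 of 5 measured members rose and 0 fell (5 rose and 0 fell when adjusted over the list alone). Hbb-bs was among them, at 71.4 ± 2.404 against 29.8 ± 1.88 FPKM. Tested as a set, the adjusted p from camera was 0.00161 (adjusted p = 0.29 with an estimated correlation). Of the endothelial markers, 5 of 6 measured members rose and 0 fell (5 rose and 0 fell when adjusted over the list alone). An example was Plvap at 4.09 ± 0.568 against 1.25 ± 0.0281 FPKM. With median-of-ratios scaling 3 rose and 0 fell, and with quantile normalization 1 rose and 0 fell. The endothelial list did not pass camera (adjusted p = 0.0804, and adjusted p = 0.3 with an estimated correlation). Of the neuroendocrine markers, 4 of 5 measured members rose and 0 fell (4 rose and 0 fell when adjusted over the list alone). One that rose was Chga at 8.11 ± 0.314 against 2.24 ± 0.519 FPKM. With median-of-ratios scaling 1 rose and 0 fell, and with quantile normalization 1 rose and 0 fell. That list did not pass either (adjusted p = 0.116, and adjusted p = 0.329 with an estimated correlation). Only 3 neutrophil markers and 2 lymphocyte markers reached a mean of 1 FPKM, too few for a list test. All 3 of the former, among them Ltf, which is also on the Sca-1-high list, rose (also when adjusted over the list alone), S100a8 from 0.572 ± 0.444 to 6.201 ± 2.18 FPKM, and of the latter Ms4a1 rose and Cd52, listed at 1342 ± 15.3 FPKM in AR_KO and 2248 ± 17.1 FPKM in control, fell (also when adjusted over the list alone). Ms4a1 did not pass with median-of-ratios scaling (adjusted p = 0.127). With 2 of 21 members of the lymphocyte list measured, the fall of Cd52 cannot be read as a change in lymphocytes. Of the seminal vesicle products, 5 of 9 measured members rose and 4 fell (5 rose and 4 fell when adjusted over the list alone). Svs6 stood at 5053 ± 65.2 against 2209.9 ± 39.02 FPKM and Pate4 at 2796 ± 17.3 against 4621 ± 160.0 FPKM, and Svs4, at 51952 ± 1412 against 63849 ± 2855 FPKM, turned to a rise of 0.72 on the log2 scale with quantile normalization. That scaling assigns values by rank, and Svs4 ranked below Spink1 in control and above it in AR_KO. The list's median was 0.55 and its camera direction down (adjusted p = 0.897, and adjusted p = 0.905 with an estimated correlation). Svs5 (uc008nui.1, chr2:164332765-164334394), at 82562 and 79683 FPKM in AR_KO and 101792 FPKM in control replicate 1, was not tested because control replicate 2 carried the status of too many fragments.

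**Figure D3:**
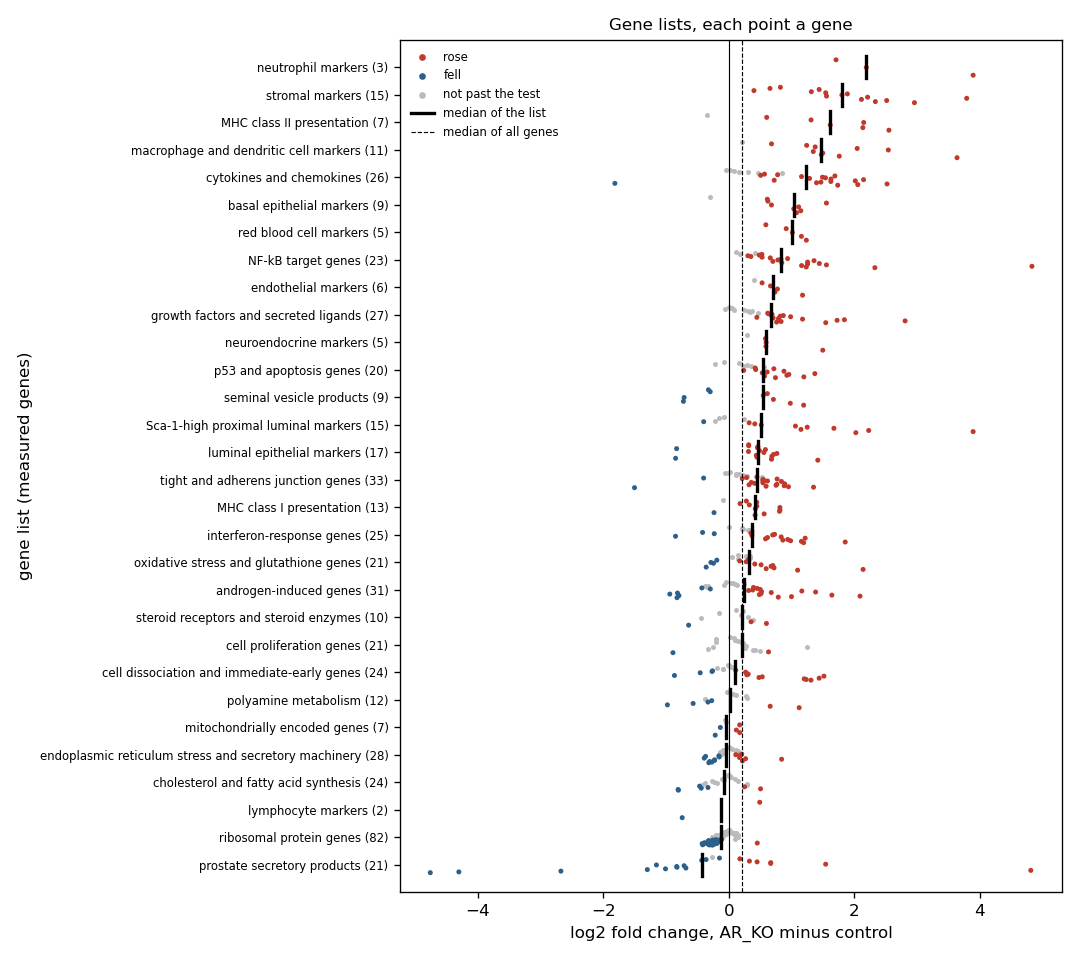
Log2 fold change (AR_KO minus control, x axis) of each measured gene in the 30 lists fixed beforehand (y axis, number of measured genes in brackets). Red points rose, blue points fell, grey points did not pass the limma test, black bars mark list medians (stromal 1.802, prostate secretory products −0.43) and the dashed line the median of all genes, 0.20.

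Of the 28 lists with at least 5 measured genes, 16 passed camera with its preset correlation, 12 up and 4 down, and none passed with a correlation estimated from these libraries (20 passed with median-of-ratios scaling and 23 with fry, which asks only whether a list's own genes move one way). With an estimated correlation, 4 libraries leave too few degrees of freedom for almost any list to pass. The stromal markers did not pass although their estimated correlation, −0.056, lay below the preset 0.01. Other lists that passed with the preset lay above it, among them the red blood cell (0.24), MHC class II (0.124), basal (0.122) and ribosomal protein lists (0.06). For such lists the preset may be too low and its camera p-values too small.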

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

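Transcripts that received no gene name were examined only after the comparison of named genes had been seen, and no test was run on them. Of 138 such transcripts with a mean of at least 1 FPKM, 8 had non-overlapping groups and were at least 2-fold higher in AR_KO, and 3 were at least 2-fold lower. With no effect, 33.3% would have non-overlapping groups at any fold. The most abundant of the 8 was uc007hxv.1 (chr11:6006288-6008328, mm10), which lies within the extent of Camk2b and was listed at a mean of 567 FPKM in AR_KO (573 and 561) and 247 FPKM in control (246 and 248). These transcripts are listed because they lie outside the comparison of named genes and were picked for values above control. Among the genes tested, 551 of 10813 met the same limits.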

How the results depend on the processing

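Leaving out genes listed at 0 in any library was chosen after the data were seen, and the other settings before. The count of genes past the limma test was 4154 as reported, 4065 and 4215 with a pseudocount of 0.1 and 5, 3241 without a filter, 3116 with a mean of at least 5 FPKM, 3583 without the trend, 2798 with the highest transcript alone and 4385 without genes listed at 0. Leaving out 1 library gave 1499 to 3351 genes, 1174 to 2726 higher and 325 to 632 lower, with a log2 fold change of Ar from −0.73 to −0.55. The lone library left in a group was assumed to vary like the other group. The counts fell most without AR_KO replicate 1 (1553) or 2 (1499), where the call of Ar was lost (−0.57, adjusted p = 0.0841, and −0.71, adjusted p = 0.0547). Besides Ar, 46 of 259 named genes and lists lost their call without AR_KO replicate 1 and 46 without AR_KO replicate 2, against 20 and 18 without control replicates 1 and 2. The 259 include genes and lists that had no call to lose, so the share of calls lost was higher than these counts imply. Bst2, Cyp2f2, Esr1, Mcm4, Ms4a1, Nkx3-1, Pbsn and Krt5 were among the genes that lost their call without at least 1 library. With the highest transcript alone, 2216 genes were higher, and Ar stood at −0.47 (adjusted p = 0.0782). Genes apart by at least 2-fold numbered 677 as reported, 1094 and 245 with a pseudocount of 0.1 and 5, which sets the size of a log2 difference at low values, and 356 with a mean of at least 5 FPKM, where fewer genes were counted.

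Median-of-ratios scaling gave 1571 genes higher and 1794 lower (46.7% higher, against 80.7% as deposited), and quantile normalization 1457 and 1436 (50.4%). Of the named genes past the test as deposited or with the scaling in question, median-of-ratios scaling turned the log2 fold change of Pbsn to −0.0626, H2-D1 to −0.0578, Ctnnb1 to −0.023, Egf to −0.216, Hspa5 to −0.0216, Hsp90b1 to −0.127, Pdia3 to −0.0678, Atf3 to −0.128, Fos to −0.21, Scd2 to −0.226, Oaz1 to −0.176, Prdx6 to −0.18, Prdx1 to −0.0637, mt-Co2 to −0.0649, mt-Atp6 to −0.119 and mt-Co1 to −0.0659. Quantile normalization turned B2m to 0.032 and Svs4 to 0.72. Another 8 and 13 named genes, past the test in neither, also changed sign with these scalings. Median-of-ratios scaling lowers AR_KO against control for every gene by construction. Quantile normalization assigns values by rank. Spink1 lay above Svs4 in control and below it in AR_KO, so the rise of Svs4 reflects its rank and not its FPKM, which fell. For B2m the cause was not tested. Of 28 lists, 16 passed camera as reported, 0 with an estimated correlation and 23 with fry. Hardly any list could pass with a correlation estimated from 4 libraries. The sample number as a replicate block gave 4475 genes, 4081 of them shared with the 4154, and same-numbered libraries did not deviate together (correlation 0.009). In a simulation that changed 200 of 10813 genes, 37 of 100 2-fold changes passed. With so few changed genes the adjusted threshold is stricter than in the data, where 4154 passed, so this is not the share recovered here. With 2 libraries per group, a gene that did not pass is still not shown to be unchanged.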

Other observations

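The limma test and its alternative scalings were chosen before the data were examined. The grouping into families, the shift predicted from abundant genes, the permutation test across cell types, the test of overlaps and the use of scaled counts to weigh explanations were chosen after the results had been seen. Gene families grouped by the start of their symbol gave 322 groups with at least 5 tested genes, of which 19 passed camera with its preset correlation and 0 with an estimated one (adjusted p = 0.97 for each of the 19). With 4 libraries hardly any family could pass the latter test. Of the small proline-rich (Sprr) genes, which encode cornified-envelope proteins, 7 of 9 rose and 0 fell (adjusted p = 1.98e-04), with Sprr1a at 1769 ± 45.4 against 542 ± 15.98 FPKM (AR_KO against control), Sprr2f at 742 ± 12.6 against 193 ± 20.03 FPKM and Sprr2g at 272 ± 4.13 against 52.4 ± 1.67 FPKM. Copies of this family share reads. Of the keratin genes 11 of 12 rose and 0 fell (adjusted p = 2.29e-04), and of the insulin-like growth factor binding proteins 5 of 6 rose and 0 fell (adjusted p = 0.027), with Igfbp7 at 119 ± 3.17 against 34.99 ± 6.53 FPKM. These counts were equal with median-of-ratios scaling. Igfbp7 was higher in the same libraries as the stromal markers. The keratins include the basal Krt5, Krt14, Krt15 and Krt17, which are themselves on the list of basal markers, of which 8 of 9 rose. Of the secretoglobins 0 of 5 rose and 5 fell (camera adjusted p = 1.03e-08). Near-identical copies of this family can share reads too, so these are not 5 independent falls, and the p-value is likely too small. Of the beta-defensins 0 of 6 rose and 5 fell (adjusted p = 7.61e-06). Of the histone genes 0 of 57 rose and 14 fell (adjusted p = 1.76e-10), a number of falls that was 25 with median-of-ratios scaling.

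More genes were called higher than lower in AR_KO, and the 10 most abundant control genes with an accepted value in every library took 27.0% of the implied fragments in control and 19.8% in AR_KO. This loss alone predicts a shift of 0.137 in log2 FPKM of all other genes, 67.0% of the median of 0.205. That median is on log2(FPKM + 1), which compresses shifts, and was 0.236 at a pseudocount of 0.1, so on this count alone 67.0% is too high a share. A few abundant transcripts may still account for much of the median shift. Sbp and Svs5, without a value in 2 and 1 control libraries, were not among the 10. The predicted shift was 0.131 (63.9% of 0.205) with these genes out of all totals. It was 0.162 (79.1%) with Svs5 added and control replicate 1 alone, so leaving Svs5 out may make the share too low. The share is therefore uncertain in both directions. Of the genes called at 2-fold or more, 67.1% were higher with median-of-ratios scaling and 81.5% as deposited, which argues against scaling as the whole cause of the excess among large changes. A response of the cells to the loss of AR stays open and was not tested separately.

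Markers of cells other than luminal cells were higher in AR_KO, although the cells had been sorted. A lower share of luminal cells would raise all other markers alike only if it acted alone and luminal cells did not express them. The 6 lists differed (permutation test with 100000 permutations, p = 0.0001). Their median log2 fold changes at a pseudocount of 0.1 were 2.29 for macrophages, 2.17 for stroma, 1.14 for endothelium, 1.13 for basal cells, 1.04 for red blood cells and 1.02 for neuroendocrine cells. The test took genes as independent and all 6 medians were above 0. It therefore cannot decide whether a lower luminal share contributed. With median-of-ratios scaling 23 of 26 stromal and macrophage markers were still past the test as higher, which argues against scaling for these 2 lists. The other lists lost more of their calls. Rises went from 8 to 6 for basal (with 1 fall), 5 to 4 for red blood cell, 5 to 3 for endothelial and 4 to 1 for neuroendocrine markers. Their medians stayed at 0.46 to 0.82. Scaling may account for part of the calls in those lists. More stromal cells and macrophages in the sort, or their free RNA, cannot be told apart from expression in the luminal cells. Of the 26 stromal and macrophage markers 25 rose as deposited, but by amounts that differed. At a pseudocount of 1, the interquartile range was 0.90 for stroma and 0.61 for macrophages, against 0.26 and 0.33 for 2 median standard errors.

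Genes called although listed at 0 in both libraries of a group numbered 24. Of these, 17 (70.8%) have exons that overlap another tested gene, against 470 of 4130 other called genes (11.4%, Fisher's exact test, two-sided, p = 1.82e-11). The division of unstranded reads between overlapping transcripts is a candidate explanation for those genes. No biological explanation was tested for them.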
